A study of Homo sapiens with 11 samples.

How the data were processed

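RNA of MCF7 cells, a human breast cancer line that carries the estrogen receptor, was measured on single-colour Agilent expression arrays. Per the labels' protocols, cells were starved of hormone for 3 days, pretreated for 1 h with 100 nM BI2536 or with DMSO, and induced for 6 h with 10 nM estradiol or with ethanol. Total RNA was purified with an RNeasy kit, and 100 ng was labelled with Cy3 by the Low Input Quick Amp protocol. Scanner files of 10 arrays were used, on 3 slides. They held 2 arrays each of DMSO with ethanol and DMSO with estradiol, and 3 each of BI2536 with ethanol and BI2536 with estradiol. The authors' value table held 11 samples, among them a replicate 3 of DMSO with ethanol whose scanner file was not used here. The submitters left out replicate 3 of DMSO with estradiol for poor hybridization, per the series design text. The labels call the samples of a group biological replicates without saying that each came from its own culture, so the p-values measure only the spread between these samples, which may be technical.

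The intensity values were produced by Feature Extraction 10.7.3.1 with the protocol GE1_107_Sep09 and probe positions on hg19, per the file headers. The processed signal, an intensity in linear units that the scanner software had corrected for background, was used as deposited. The authors' value table holds log2 values for 25526 probes, all of which matched a probe name of the scanner files. Its columns had medians of 9.06 (replicates 1 and 3 of DMSO with ethanol, replicate 1 of DMSO with estradiol, replicate 3 of BI2536 with ethanol), 9.07 (replicate 2 of DMSO with ethanol) and 9.08 (the other 6 samples). On the 10 shared arrays they correlated with the log2 mean signal at r from 0.9988 to 0.9998 across probes and with the log2 processed signal at r from 0.9845 to 0.9889, so the values were log2 and were not centred per gene. The near-equal distributions resemble quantile normalization, but the method is not given in the sources used here, so the table served only as an alternative.

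Of 44495 spots, 43118 were not controls. Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged, which left 34127 probes. From log2 of the processed signal the 75th percentile of each array was subtracted. A probe was kept where it was well above background, by the scanner software's own flag on at least 50% of its spots, on every array of at least 1 group (25836 probes). Each gene was represented by the probe with the highest mean over all arrays, which gave 20789 genes, 18 of them with a missing value. Probes were named through a RefSeq table of GRCh38.p14, by accession for 24826, by symbol for 1188 and by a synonym for 472, and 7641 kept the name in the file. Positions are those of the scanner files. Of the 200 named genes with a chromosome in both sources, 3 (PLK1, UHRF1 and NOP56) had a probe that the scanner files place on another chromosome than the table's gene.

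Between 71.9% and 77.6% of probes were well above background per array, the 75th percentile of the signal lay between 1618 and 2363, and 1 spot was saturated. Arrays of the same group correlated at r from 0.9875 to 0.9951 across the genes without a missing value. The number of arrays limits the precision.

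Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, two-sided, Benjamini-Hochberg adjusted over the genes tested, threshold 0.05), with all 10 arrays in the same fit and group means only. The comparisons were estradiol against ethanol after DMSO, the same after BI2536, BI2536 against DMSO without estradiol, the same with estradiol, and the interaction, which is the estradiol change after BI2536 less that after DMSO. The interaction was also tested over only the genes that responded to estradiol in an additive model, whose estimate is independent of the interaction. The filter was that model's adjusted p, whose spread contains the interaction. Genes with a strong interaction, such as opposite responses in both arms, were therefore less likely to enter. A gene whose probe was not well above background on any array of a group has only a bound there: it is the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own signal and the lowest signal among probes well above background.

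20 gene lists were fixed before the data were examined: estrogen-induced genes of breast cancer cells, estrogen-repressed genes, the estrogen receptor and its cofactors, polo-like kinases, G2 and mitosis genes, G1/S and DNA replication genes, p53 targets, immediate early and AP-1 genes, ribosome biogenesis genes, genes raised by BET bromodomain inhibitors in other cells, interferon-stimulated genes, NF-kB and inflammatory genes, TGF-beta and BMP pathway genes, unfolded protein and integrated stress response genes, heat shock genes, aryl hydrocarbon receptor targets, cholesterol synthesis genes, luminal epithelial markers, basal epithelial and mesenchymal markers, and stromal, endothelial and blood cell markers. The lists were written from general knowledge. They were tested with camera at a preset correlation of 0.01 and adjusted over the 20 lists. With an estimated correlation, 5 of 9 calls held for estradiol after DMSO, 5 of 6 for estradiol after BI2536, 3 of 11 for BI2536 without estradiol, 3 of 7 for BI2536 with estradiol and 1 of 7 for the interaction. The directional test fry called 15, 11, 15, 15 and 8 lists, but it does not compare a list with other genes. The rule for named genes was also fixed beforehand. It took the 10 rising and 10 falling genes with the largest log2 fold change among those that passed with no overlap between arrays (no such condition for the interaction), up to 4 members per list that passed, and TFF1, GREB1, PGR, MYC, CCND1, CXCL12, ESR1, PLK1, CDKN1A and HEXIM1 always. Genes that repeated a group already described were left out.

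The replicate number equals the slide. Slides 1 and 2 hold all 4 groups and slide 3, in the scanner files used, only both BI2536 groups. Deviations from the group means correlated between arrays of the same slide at r from 0.116 to 0.673 (median 0.251, 13 pairs). Correlations of arrays on different slides are bound to these, since deviations in a group sum to 0. Over all 144 regroupings of the slide numbers within groups the mean same-slide r of 0.337 (highest regrouping 0.372) had p = 0.0417 (exact permutation test, one-sided, chosen after seeing the data), so the numbers were taken to pair the samples through the slide. The slide was a fixed block in an alternative fit. Simulated data of 20771 genes held 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 3-fold in each comparison. Of the 67 genes changed 2-fold limma recovered 49.3% for estradiol after DMSO and 62.7% after BI2536. For BI2536 it recovered 65.7% without and 73.1% with estradiol, and for the interaction 44.8%. False calls numbered 5, 3, 7, 7 and 8 in that order. The simulated noise was independent between arrays, without a slide effect. Far fewer genes changed than were called for estradiol or BI2536 in the data, so these shares do not give the power there. Alternatives were normexp background correction (offset 50), quantile and median scaling, the authors' table with 11 and with 10 samples, no filter on dim probes or a filter on every array, every probe on its own, the slide as a fixed or a random block, only the groups compared in the fit, an intensity trend, and leaving out each array in turn. A fit of only slides 1 and 2 was chosen after seeing the data.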

Results

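MCF7 cells are a human breast cancer line that grows in response to estrogen. They were treated with estradiol, the main estrogen, or with its solvent ethanol, after pretreatment with BI2536 or with its solvent DMSO. BI2536 is a small-molecule inhibitor of polo-like kinase 1 (PLK1), a kinase of mitosis, and is also known to bind BET bromodomain proteins. The series asks whether PLK1 signalling acts together with the estrogen receptor in transcription. Values are log2 fold changes ± standard error from limma with its adjusted p. They rest on 2 arrays each of DMSO with ethanol and DMSO with estradiol and 3 each of BI2536 with ethanol and BI2536 with estradiol.

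Estradiol after DMSO raised 42 of the 48 measured estrogen-induced genes (43 adjusted over the list alone) and lowered none of them. CXCL12, a chemokine gene (probe on chromosome 10, 44872888 to 44872947, hg19), rose by 3.13 ± 0.09 (adjusted p = 7.46e-06). PGR, the progesterone receptor gene (chromosome 11, 100912709 to 100912768), rose by 2.76 ± 0.07 (adjusted p = 7.46e-06), from -3.09 ± 0.02 to -0.33 ± 0.05 (SD, n = 2 each) relative to the array's 75th percentile. GREB1, a coactivator of the estrogen receptor (chromosome 2, 11782680 to 11782739), rose by 3.17 ± 0.42 and TFF1, a secreted trefoil peptide, by 1.19 ± 0.08. EGR3, an immediate early transcription factor, was not well above background without estradiol and was at least 16.5-fold higher with it (adjusted p = 0.00233). NEFH, the heavy neurofilament gene, was at least 8.29-fold higher (adjusted p = 2.69e-05) and VXN at least 20-fold higher (adjusted p = 0.00119), both also not well above background without estradiol. CCND1, the cyclin D1 gene, did not pass (0.20 ± 0.08, adjusted p = 0.121).

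Of 23 estrogen-repressed genes, 20 fell (22 adjusted over the list alone) and 1 rose. BMF, a pro-apoptotic gene of the BH3-only family (chromosome 15, 40380450 to 40380509), fell by 2.33 ± 0.08 (adjusted p = 8.34e-06), BTG2, an antiproliferative gene, by 1.61 ± 0.11 and TP53INP1 by 1.69 ± 0.10. The riser was TGM2, a transglutaminase (2.00 ± 0.10, adjusted p = 3.13e-05). Other genes with large falls were CYP1A1, a cytochrome P450 of xenobiotic metabolism (-2.75 ± 0.17), WNT11, a Wnt ligand (-2.37 ± 0.14), and HCAR3, a metabolite receptor (-2.33 ± 0.08). ESR1, the estrogen receptor alpha gene, fell by 0.46 ± 0.07 (adjusted p = 0.00277). Camera called the induced list (mean shift 1.29, adjusted p = 1.62e-35) and the repressed list (-0.82, adjusted p = 3.8e-14).

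Growth genes rose with estradiol after DMSO. Of 31 G1/S and DNA replication genes 26 rose and none fell (29 adjusted over the list alone; camera adjusted p = 3.21e-21), among them CDC25A, a phosphatase that activates cyclin-dependent kinases (1.23 ± 0.08). Of 26 ribosome biogenesis genes 24 rose and none fell (25 adjusted over the list alone; camera adjusted p = 1.12e-21), with RRS1 at 1.14 ± 0.07 and LYAR at 1.11 ± 0.10. MYC, a transcription factor that drives growth, rose by 1.17 ± 0.08 (adjusted p = 0.000109). Of 38 G2 and mitosis genes 2 rose and 3 fell (camera adjusted p = 0.936), and PLK1 itself did not pass (-0.00 ± 0.20, adjusted p = 0.999). That PLK1 probe, used in all comparisons, is placed on chromosome 8 by the scanner files, so whether it reads PLK1 is uncertain. The other PLK1 probe, on the gene's own chromosome 16, did not represent the gene. It had the opposite sign here, which tells little beside -0.00 ± 0.20. Of 5 polo-like kinases PLK3 rose and PLK2 fell (camera adjusted p = 0.962). The PLK3 call was lost without any 1 of the 4 arrays of these groups (highest adjusted p 0.0911).

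Of 18 TGF-beta and BMP pathway genes 9 fell and none rose (9 adjusted over the list alone; camera adjusted p = 1.7e-05), including the ligand genes TGFB2 (-1.16 ± 0.10) and TGFB3 (-1.15 ± 0.12). Of 18 interferon-stimulated genes 10 fell and none rose (12 adjusted over the list alone; mean shift -1.09, camera adjusted p = 1.04e-05), with IFI6 at -1.26 ± 0.19. The calls of IFIT1, OAS1 and IRF9 were lost in 7, 8 and 2 of 10 fits that left out an array, and that of IFI6 in none. The list's call was lost at an adjusted p = 0.145 with an estimated correlation. Of 8 aryl hydrocarbon receptor targets 5 fell and TIPARP, an ADP-ribosyltransferase, rose by 1.28 ± 0.07 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0103). AHRR, the receptor's repressor, fell by 1.77 ± 0.07, and the list had an adjusted p = 0.0789 with an estimated correlation. Of 12 heat shock genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0203), at an adjusted p = 0.0902 with an estimated correlation and 0.0583 without replicate 1 of DMSO with ethanol. The heat shock genes called were HSPA8, HSPH1 and HSPD1, whose calls were lost in 3, 7 and 9 of 10 fits that left out an array. Of the 12 genes raised by BET inhibitors in other cells SERPINI1 rose, and HEXIM1 and H2BC21 fell (1 and 4 adjusted over the list alone; camera direction down, adjusted p = 0.0247; adjusted p = 0.145 with an estimated correlation). HEXIM1, an inhibitor of the elongation factor P-TEFb, fell by 0.47 ± 0.13 (adjusted p = 0.0424). The calls of HEXIM1, H2BC21 and SERPINI1 were lost in 7, 8 and 8 of 10 fits that left out an array (highest adjusted p 0.211, 0.178 and 0.201), and that of SERPINI1 with the slide as a block (0.0677). SERPINI1 was not well above background without estradiol, and normexp reversed its direction (-0.12). The mean of that list was -0.06 and its median -0.23, with means of 0.06 within slide 1 and -0.17 within slide 2. It was lost without replicate 2 of DMSO with ethanol (mean 0.03, adjusted p = 0.155) and without replicate 1 of DMSO with estradiol (adjusted p = 0.0604).

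The remaining lists were not called. Among p53 targets 4 of 27 rose and 8 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.0707, and 0.042 with the slide as a block), with PMAIP1, a BH3-only gene, up by 2.01 ± 0.09 and CDKN1A, the p21 gene, at -0.39 ± 0.20 (adjusted p = 0.263, and 0.0138 with the slide as a block). Among immediate early genes 6 of 26 rose and 3 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.306), with FOS up by 1.62 ± 0.08. Counts of genes that rose and fell were 3 and 1 of 13 NF-kB genes (5 and 2 adjusted over the list alone), 4 and 4 of 18 receptor and cofactor genes (4 and 5), 1 and 4 of 16 stress response genes (2 and 5), 0 and 2 of 16 cholesterol synthesis genes (0 and 2), and 2 and 3 of 13 luminal markers (2 and 3). Their camera adjusted p were 0.11, 0.936, 0.52, 0.79 and 0.936, and the cholesterol list's mean (-0.02) and median (0.05) differed in sign. Markers of other cells also moved. The adhesion receptor gene CD44 rose by 1.34 ± 0.07, the caveolin gene CAV1 by 0.79 ± 0.09 and the endothelial gene VWF by 1.57 ± 0.11, while the basal and mesenchymal list (3 of 9 rose, adjusted p = 0.0727) and the stromal, endothelial and blood list (2 of 10 rose, adjusted p = 0.214) did not pass.

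In all, limma called 3640 of 20789 genes for estradiol after DMSO, 1805 higher and 1835 lower, with a median absolute log2 fold change of 0.54. Of these, 850 rose and 730 fell at least 1.5-fold. Within slide 1 and within slide 2 the medians toward the pooled sign were 0.55 and 0.53. As here, genes in such medians were chosen on the pooled value that the slides make up, so these are no replication. With the slide as a block 5967 genes were called, against 1248 with normexp background correction and 231 in a fit of only these 4 arrays, where the calls of GREB1, TFF1, MYC, ESR1, VXN, TGFB2, TGFB3, IFI6, PLK2, PLK3 and CAV1 were lost. Normexp ended the calls of NEFH, TGFB2 and VWF, and leaving out replicate 1 or 2 of DMSO with ethanol, or replicate 1 or 2 of DMSO with estradiol, gave 2294, 2218, 2114 and 2306 genes.

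After BI2536, estradiol again raised most estrogen-induced genes, 40 of 48 (42 adjusted over the list alone), and lowered none of them. PGR rose by 2.54 ± 0.06 (adjusted p = 4.34e-06), from -3.29 ± 0.03 to -0.75 ± 0.08 (SD, n = 3 each). CXCL12 rose by 2.36 ± 0.07, GREB1 by 2.66 ± 0.34, MYC by 1.36 ± 0.06 and TFF1 by 0.90 ± 0.06. The largest rises with signal in both groups were those of RBM24, an RNA-binding protein gene (3.43 ± 0.15), RUBCNL (3.13 ± 0.20, well above background on 1 of 3 arrays without estradiol) and the keratin gene KRT13 (2.79 ± 0.10). HEY2, a Notch pathway repressor, rose by 2.42 ± 0.07. Of 23 estrogen-repressed genes 18 fell and TGM2 rose (1.74 ± 0.08), which is 20 and 1 adjusted over the list alone. Among large falls were PSCA, a cell surface antigen gene (-1.82 ± 0.11), BMF (-1.66 ± 0.06) and ALDH1A3, a retinaldehyde dehydrogenase (-1.66 ± 0.06). ESR1 fell by 0.49 ± 0.05 (adjusted p = 0.00087).

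G1/S genes rose after BI2536 (24 of 31, 27 adjusted over the list alone), with CDC25A at 1.00 ± 0.07 and MCM10 at 0.89 ± 0.06, as did ribosome biogenesis genes (24 of 26, 25 adjusted over the list alone), with NOP16 at 1.17 ± 0.06 and RRS1 at 1.16 ± 0.06. Of 18 TGF-beta and BMP genes 10 fell and none rose (10 adjusted over the list alone), with TGFB3 at -1.13 ± 0.10 and SMAD3 at -0.59 ± 0.07. Camera gave adjusted p = 3.03e-35 for the induced list, 6.99e-14 for the repressed list, 4.29e-21 for G1/S, 3.46e-24 for ribosome biogenesis and 4.95e-07 for TGF-beta. Of the 12 genes raised by BET inhibitors in other cells 2 fell, H1-0 and ZCCHC24 (2 adjusted over the list alone; mean shift -0.19, camera adjusted p = 0.0175), and that call had an adjusted p = 0.14 with an estimated correlation. In fits that left out an array the H1-0 call was lost in 5 of 10 and that of ZCCHC24 in 6 of 10 (highest adjusted p 0.0923 and 0.102). HEXIM1 did not pass (-0.08 ± 0.11, adjusted p = 0.709). PLK1 (-0.14 ± 0.16, adjusted p = 0.68), CCND1 (0.17 ± 0.06, adjusted p = 0.109) and CDKN1A (-0.44 ± 0.16, adjusted p = 0.125, and 0.00536 with the slide as a block) did not pass either.

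Interferon-stimulated genes, called down with estradiol after DMSO (adjusted p = 0.145 with an estimated correlation), were not called after BI2536 (1 of 18 fell, 0 adjusted over the list alone; mean shift -0.29, camera adjusted p = 0.229). Heat shock genes had an adjusted p = 0.0555, and 0.0273 with the slide as a block. CYP1A1 fell by 1.03 ± 0.14 and TIPARP rose by 0.75 ± 0.06, but the aryl hydrocarbon receptor list was not called (1 of 8 rose and 3 fell, adjusted p = 0.0809). The other lists, among them G2 and mitosis (1 of 38 rose and 1 fell, adjusted p = 0.965), polo-like kinases (1 of 5 rose and 1 fell, adjusted p = 0.965) and p53 targets (4 of 27 rose and 7 fell, adjusted p = 0.361), were not called. CD44 rose by 0.64 ± 0.06 and VWF by 0.46 ± 0.09 beside them. The VWF call was lost with normexp, with the authors' 11 samples and on slides 1 and 2 alone. Limma called 3467 genes, 1663 higher and 1804 lower, with a median absolute log2 fold change of 0.42, and medians toward the pooled sign of 0.42, 0.42 and 0.43 within slides 1, 2 and 3. With the slide as a block the count was 5998, with normexp 1161, on slides 1 and 2 alone 1361 (chosen after seeing the data) and without replicate 3 of BI2536 with estradiol 2310.

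The estradiol responses after DMSO and after BI2536, which share no array, were set side by side. 1277 genes rose and 1287 fell in both, where independent lists of the same sizes would share 144.4 and 159.2, and 3 were called in opposite directions. Both comparisons take each gene's spread from the same fit, so some excess over independent lists can arise from that alone, without regard to direction. Across the 20789 genes the fold changes correlated at r = 0.574, and genes are not independent replicates. The shared calls numbered 4387 with the slide as a block, 850 with normexp and 1212 on slides 1 and 2 alone. They numbered 1691 without replicate 2 of DMSO with ethanol and 1647 without replicate 1 of DMSO with estradiol.

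**Figure D1:**
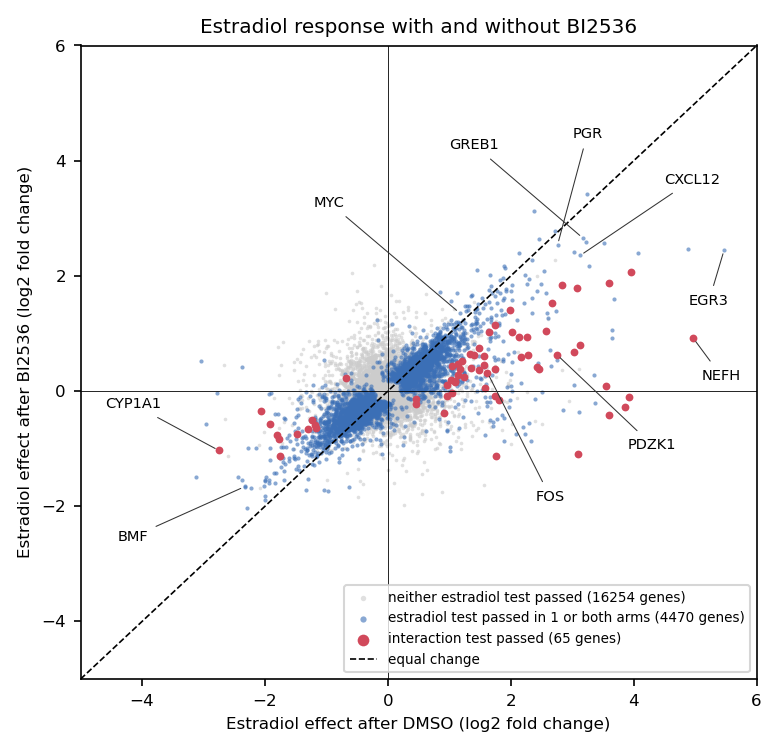
Log2 fold change with estradiol after DMSO (x axis) against after BI2536 (y axis) for the 20789 genes tested, with genes called for estradiol and the 65 genes called for the interaction in their own colours. The slope was 0.716 for the 5748 genes that responded to estradiol in the additive model, and noise in the values after DMSO lowers such a slope by itself.

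The interaction asked whether the estradiol response differed after BI2536. P2RY6, a nucleotide receptor gene (chromosome 11, 73008625 to 73008684), fell by 1.92 with estradiol after DMSO and by 0.57 after BI2536, a difference of 1.35 ± 0.11 (adjusted p = 0.00885). UGT2B15, a steroid glucuronosyltransferase gene (chromosome 4, 69512758 to 69512817), rose by 2.43 after DMSO and 0.41 after BI2536 (difference -2.01 ± 0.16, adjusted p = 0.00885). PLIN4, a lipid droplet protein gene, rose by 2.46 and 0.39 (-2.07 ± 0.16, adjusted p = 0.00885). FOS rose by 1.62 and 0.32 (-1.30 ± 0.11, adjusted p = 0.00885), a call that ended without replicate 2 of DMSO with ethanol (adjusted p = 0.0513). NEFH, not well above background without estradiol in either arm, had a fitted difference of -4.05 ± 0.31 (adjusted p = 0.00885). For CXCL12 the difference was -0.77 ± 0.12, which did not pass over all genes (adjusted p = 0.056) and passed over the genes that responded to estradiol (adjusted p = 0.0199). Over all genes it was for TFF1 -0.29 ± 0.10 (0.535), for PGR -0.22 ± 0.09 (0.697), for GREB1 -0.52 ± 0.55 (1), for MYC 0.19 ± 0.10 (0.934) and for ESR1 -0.03 ± 0.08 (1). These 5 did not pass, nor did HEXIM1 (0.39 ± 0.17, 0.733), PLK1 (-0.14 ± 0.26, 1), CCND1 (-0.03 ± 0.10, 1) and CDKN1A (-0.04 ± 0.26, 1).

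The estrogen-induced list was shifted down in the interaction (mean -0.27, camera adjusted p = 2.15e-07), with 2 of 48 genes called, none up (9 adjusted over the list alone), and it also held with an estimated correlation (adjusted p = 0.01). The 2 were PDZK1 and CCN5, whose calls were lost in 8 and 10 of 10 fits that left out an array (highest adjusted p 0.182 each). The estrogen-repressed list was shifted up (mean 0.14, camera adjusted p = 0.00205; 0 of 23 called, 1 up adjusted over the list alone; adjusted p = 0.211 with an estimated correlation) and G1/S genes down (-0.11, 0.000136; 0 of 31 called; adjusted p = 0.128 with an estimated correlation). Interferon-stimulated genes were shifted up (0.81, 4.36e-08; 0 of 18 called, 2 adjusted over the list alone), at an adjusted p = 0.128 with an estimated correlation. Aryl hydrocarbon receptor targets were shifted up (0.37, 0.018; CYP1A1 and AHRR called of 8; adjusted p = 0.128 with an estimated correlation), a call lost without replicate 2 of DMSO with ethanol (0.105) or replicate 3 of BI2536 with ethanol (0.0527). The gene calls were lost in 8 of 10 such fits for CYP1A1 (highest adjusted p 0.129, and 0.0633 with the slide as a block) and in 3 for AHRR (0.059). NF-kB genes were shifted down (-0.18, 0.0249; 0 of 13 called, 2 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), lost without replicate 2 of DMSO with ethanol (0.118) or replicate 1 of DMSO with estradiol (0.106). Basal and mesenchymal markers were shifted down (-0.25, 0.00294; CD44 called of 9, 2 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation). With normexp the means of the NF-kB and basal lists were 0.17 and 0.08, with a median of all genes of 0.12. VWF was the only called member of 10 stromal, endothelial and blood markers (-1.11 ± 0.14, list adjusted p = 0.0791). Leaving out an array ended the CD44 call in 10 of 10 fits (highest adjusted p 0.123) and that of VWF in 9 (0.154). The receptor and cofactor list and the p53 list had adjusted p = 0.053 each, and 0.0352 and 0.0124 with the slide as a block, and the other lists did not pass. For genes raised by BET inhibitors the mean (-0.14), the median (0.03) and the test's direction (up, adjusted p = 0.667) differed in sign.

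Limma called 65 genes for the interaction, 12 higher and 53 lower (medians of 1.14 within slide 1 and 1.03 within slide 2 toward the pooled sign, for genes chosen on that value). Among the 5748 genes that responded to estradiol in the additive model 95 were called, all with a weaker response after BI2536, of which 68 were induced and 27 repressed. All 5748 had a median difference toward the estradiol change of -0.06, with 66% weaker after BI2536. The 309 genes changed at least 2-fold had median responses of 1.55 after DMSO and 1.17 after BI2536, and 80.9% of them were weaker after BI2536, with a median difference toward the estradiol change of -0.34 (-0.35 within slide 1 and -0.31 within slide 2). The count of 65 became 118 with the slide as a fixed block, 259 as a random block and 36 without a filter on dim probes. Leaving out replicate 1 or 2 gave 17 and 11 for DMSO with ethanol and 28 and 31 for DMSO with estradiol. Leaving out replicate 1, 2 or 3 gave 32, 31 and 22 for BI2536 with ethanol and 20, 27 and 24 for BI2536 with estradiol. Among responsive genes the count of 95 became 19, 23, 11 and 13 without those DMSO arrays in turn, 61 without replicate 1 of BI2536 with ethanol, and 51 and 50 without replicates 1 and 3 of BI2536 with estradiol. With normexp and limma the count of 65 over all genes was 0 (475 at an unadjusted p under 0.05, lowest adjusted p 0.137), and on slides 1 and 2 alone, chosen after seeing the data, it was 0 (1249, lowest 0.136).

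BI2536 without estradiol raised all 12 listed genes raised by BET bromodomain inhibitors in other cells (12 adjusted over the list alone). That list was written from general knowledge. SERPINI1, a serine protease inhibitor gene not well above background without BI2536, was at least 8.59-fold higher (adjusted p = 0.000707), ZCCHC24 rose by 1.52 ± 0.07 (adjusted p = 2.58e-05) and HEXIM1 (chromosome 17, 43229082 to 43229141) by 1.02 ± 0.12 (adjusted p = 0.000875). The other 9 members are histone genes, whose sequences are close, so which of them rose is uncertain, with H2BC21 at 0.82 ± 0.07. The list's mean shift was 1.03 (camera adjusted p = 2.44e-10; adjusted p = 0.0181 with an estimated correlation), 1.08 within slide 1 and 0.97 within slide 2. Of 38 G2 and mitosis genes 24 rose and none fell (25 adjusted over the list alone; camera adjusted p = 4.26e-11), with BUB1, a spindle checkpoint kinase gene, at 0.68 ± 0.07, CDCA8 at 0.60 ± 0.06 and CDC20 at 0.53 ± 0.09. That call had an adjusted p = 0.0846 with an estimated correlation. PLK1, by the uncertain probe on chromosome 8, did not pass (0.32 ± 0.18, adjusted p = 0.282, and 0.0176 with the slide as a block). Of 5 polo-like kinases 2 rose, PLK3 and PLK5 (2 adjusted over the list alone). Camera gave that list an adjusted p = 0.033, and 0.221 with an estimated correlation. The PLK3 and PLK5 calls were lost in 2 and 3 of 10 fits that left out an array (highest adjusted p 0.0715 and 0.129). The polo list was lost without replicate 1 of DMSO with ethanol (0.0618) or replicate 2 of BI2536 with ethanol (0.0506).

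Other genes with large rises were SORBS1, an adaptor protein gene (2.93 ± 0.11, adjusted p = 1.5e-05), and SMPD3, a neutral sphingomyelinase gene (2.49 ± 0.10). Among falls were FOXI1, a forkhead transcription factor, at least 10.1-fold lower and not well above background with BI2536 (adjusted p = 0.000321), the long noncoding RNA DIRC3 (-3.01 ± 0.11) and PLEKHS1 (-2.87 ± 0.11). ESR1 fell by 0.70 ± 0.06 (adjusted p = 0.000236) and GPER1, a membrane estrogen receptor gene, by 0.92 ± 0.06, within a receptor and cofactor list that was not called (3 of 18 rose and 6 fell, adjusted p = 0.64). Of 48 estrogen-induced genes 16 fell and 2 rose (18 and 3 adjusted over the list alone; mean shift -0.22, camera adjusted p = 0.00102; adjusted p = 0.0379 with an estimated correlation), with HSPB8 at -0.94 ± 0.09, IGFBP4 at -0.86 ± 0.10, MYC at -0.57 ± 0.07 and CXCL12 at -0.46 ± 0.08. The CXCL12 call was lost with normexp, with the authors' table and in a fit of only these groups, and 1 of its 3 other probes had the opposite sign. TFF1 (-0.02 ± 0.07, adjusted p = 0.885), PGR (-0.21 ± 0.06, 0.0555, and 0.0439 with the slide as a block) and GREB1 (-0.82 ± 0.39, 0.19, and 0.0227 with the block) did not pass, nor did CCND1 (-0.11 ± 0.07, 0.318) and CDKN1A (-0.12 ± 0.18, 0.727). Of 23 estrogen-repressed genes 9 fell and 2 rose (9 and 2 adjusted over the list alone; -0.30, camera adjusted p = 0.00702; adjusted p = 0.255 with an estimated correlation), with BMF at -1.16 ± 0.07.

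Of 13 NF-kB and inflammatory genes 6 fell and none rose (7 adjusted over the list alone; camera adjusted p = 0.000364; adjusted p = 0.0379 with an estimated correlation), with TNFAIP2 at -1.56 ± 0.08 and ICAM1, an adhesion molecule gene, at -0.89 ± 0.08. Of 18 interferon-stimulated genes 10 fell and 1 rose (14 and 1 adjusted over the list alone; mean shift -1.05, camera adjusted p = 6.46e-05), at an adjusted p = 0.202 with an estimated correlation, with the antiviral gene MX1 at -1.69 ± 0.17. Of 12 heat shock genes 4 rose (6 adjusted over the list alone; camera adjusted p = 0.00271; adjusted p = 0.062 with an estimated correlation), with HSPA1B at 0.84 ± 0.07. Aryl hydrocarbon receptor targets were called down (1 of 8 rose and 3 fell, 1 and 4 adjusted over the list alone; camera adjusted p = 0.0412; adjusted p = 0.188 with an estimated correlation), with CYP1A1 at -1.81 ± 0.15 and TIPARP at 0.69 ± 0.07. G1/S genes were called up (6 of 31 rose and 2 fell, 8 and 2 adjusted over the list alone; mean 0.10, camera adjusted p = 0.0345; adjusted p = 0.306 with an estimated correlation). Without replicate 2 of DMSO with ethanol both the receptor target and the G1/S call were lost (0.119 each), as without replicate 1 of BI2536 with ethanol (0.0591 each), and the receptor target call was also lost without replicate 3 of that group (0.0728). Cholesterol synthesis genes were called up (5 of 16 rose, 5 adjusted over the list alone; camera adjusted p = 0.0406; adjusted p = 0.202 with an estimated correlation), with LSS, the lanosterol synthase gene, at 0.42 ± 0.07. That call was lost without replicate 1 (0.0501) or 2 (0.094) of DMSO with ethanol and without replicate 2 (0.0718) or 3 (0.0569) of BI2536 with ethanol.

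TGF-beta genes were not called as a list (2 of 18 rose and 6 fell, adjusted p = 0.231), although TGFB2 fell by 2.27 ± 0.09 and TGFB3 by 1.47 ± 0.11. Neither were p53 targets (6 of 27 rose and 3 fell, adjusted p = 0.377), immediate early genes (5 of 26 and 3, 0.588), ribosome biogenesis genes (4 of 26 and 2, 0.525), stress response genes (5 of 16 and 2, 0.311) or luminal markers (0 of 13 and 3, 0.485). CAV1 fell by 1.34 ± 0.08 and VWF by 0.85 ± 0.10, while the basal list (0 of 9 rose and 2 fell, 0.222) and the stromal list (0 of 10 and 1, 0.398) were not called. Limma called 4702 genes, 2299 higher and 2403 lower, with 619 and 1213 at least 1.5-fold, and medians toward the pooled sign of 0.48 within slide 1 and 0.50 within slide 2. Of the called genes 48.9% were higher, against 65.9% under median scaling, where the median of all genes was 0.09. Counts of calls were 1516 with normexp, where those of SERPINI1, ICAM1, VWF, PLK3 and PLK5 were lost (VWF also with the authors' table), 2690 in a fit of only these groups, 3010 on slides 1 and 2 alone (chosen after seeing the data), and 2890 and 2917 without replicate 1 or 2 of DMSO with ethanol.

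BI2536 with estradiol present lowered 25 of 48 estrogen-induced genes and raised none of them (29 adjusted over the list alone; mean shift -0.49, camera adjusted p = 1.21e-10; adjusted p = 0.00352 with an estimated correlation). PDZK1, a scaffold protein gene (chromosome 1, 145924674 to 145924733), fell by 2.60 ± 0.21 (adjusted p = 0.000198), CCN5, a secreted matricellular protein gene, by 1.27 ± 0.09, CXCL12 by 1.23 ± 0.08 and PGR by 0.43 ± 0.06 (adjusted p = 0.00276). GREB1 (-1.34 ± 0.39, adjusted p = 0.0452), TFF1 (-0.31 ± 0.07, 0.0155) and MYC (-0.38 ± 0.07, 0.00798) passed. The GREB1 call was lost in 7 of 10 fits that left out an array (highest adjusted p 0.252). That of TFF1 was lost with normexp, under median scaling, in a fit of only these groups and on slides 1 and 2 alone, and without replicate 1 of DMSO with estradiol (0.116) or replicate 3 of BI2536 with estradiol (0.0509). The MYC call was lost under median scaling and without replicate 1 of DMSO with estradiol (0.0621). ESR1 fell by 0.73 ± 0.06 and GPER1 by 1.48 ± 0.06, in a receptor and cofactor list that was not called (3 of 18 rose and 4 fell, adjusted p = 0.232). CCND1 (-0.14 ± 0.07, adjusted p = 0.211), PLK1 by the uncertain probe on chromosome 8 (0.18 ± 0.18, 0.575) and CDKN1A (-0.16 ± 0.18, 0.628) did not pass.

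Of the 12 genes raised by BET inhibitors in other cells 11 rose (12 adjusted over the list alone; mean shift 0.89, camera adjusted p = 1.21e-10; adjusted p = 0.00876 with an estimated correlation), with ZCCHC24 at 1.41 ± 0.07, HEXIM1 at 1.41 ± 0.12 and H2BC21 at 0.99 ± 0.07, and the histone members again uncertain. NF-kB genes fell (8 of 13, 8 adjusted over the list alone; camera adjusted p = 1.48e-05; adjusted p = 0.0172 with an estimated correlation), among them TNFAIP2 (-1.58 ± 0.08), LIF, a cytokine gene (-1.24 ± 0.09), and ICAM1 (-1.11 ± 0.08). G2 and mitosis genes rose (23 of 38, 23 adjusted over the list alone; camera adjusted p = 1.5e-11; adjusted p = 0.0975 with an estimated correlation), among them BUB1 (0.81 ± 0.07) and HMMR (0.66 ± 0.05). Of 5 polo-like kinases 3 rose, PLK2, PLK3 and PLK5 (3 adjusted over the list alone; camera adjusted p = 0.0204; adjusted p = 0.213 with an estimated correlation). The PLK2 call was lost without replicate 1 of DMSO with estradiol (0.0877). Of 12 heat shock genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.0197; adjusted p = 0.101 with an estimated correlation). Basal and mesenchymal markers were called down (3 of 9 fell, 5 adjusted over the list alone; camera adjusted p = 0.03; adjusted p = 0.125 with an estimated correlation), with CAV1 at -1.86 ± 0.08 and CD44 at -0.98 ± 0.06, a call lost without replicate 2 of BI2536 with estradiol (0.0554). VWF fell by 1.96 ± 0.10 and COL1A1, a collagen gene, by 0.84 ± 0.10 beside a stromal list that was not called (2 of 10 fell, adjusted p = 0.194).

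Other genes with large changes were PAG1, an adaptor of Src family kinase signalling (2.56 ± 0.09), SORBS1 (2.53 ± 0.11) and TPPP, a tubulin-binding protein gene (2.22 ± 0.08), which rose, and the lysyl oxidase-like gene LOXL4 (-3.27 ± 0.31) and the cadherin gene CDH26 (-3.09 ± 0.09), which fell. Luminal markers had an adjusted p = 0.163 (2 of 13 fell), and 0.0296 with the slide as a block. The remaining lists were not called, at adjusted p from 0.0577 for cholesterol synthesis (5 of 16 rose) and 0.0733 for p53 targets (10 of 27 rose and 5 fell) to 0.901 for G1/S (2 of 31 rose and 2 fell). Interferon-stimulated genes, with 2 of 18 up and 4 down, had an adjusted p = 0.232. Limma called 4464 genes, 2139 higher and 2325 lower, with medians toward the pooled sign of 0.50 within slide 1 and 0.49 within slide 2. Of these, 47.9% were higher, against 65.5% under median scaling. The counts were 1371 with normexp, where the calls of LIF, ICAM1, COL1A1, PLK2, PLK3 and PLK5 were lost, 2734 in a fit of only these groups, 2920 on slides 1 and 2 alone (chosen after seeing the data), and 2735 and 2822 without replicate 1 or 2 of DMSO with estradiol.

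**Figure D2:**
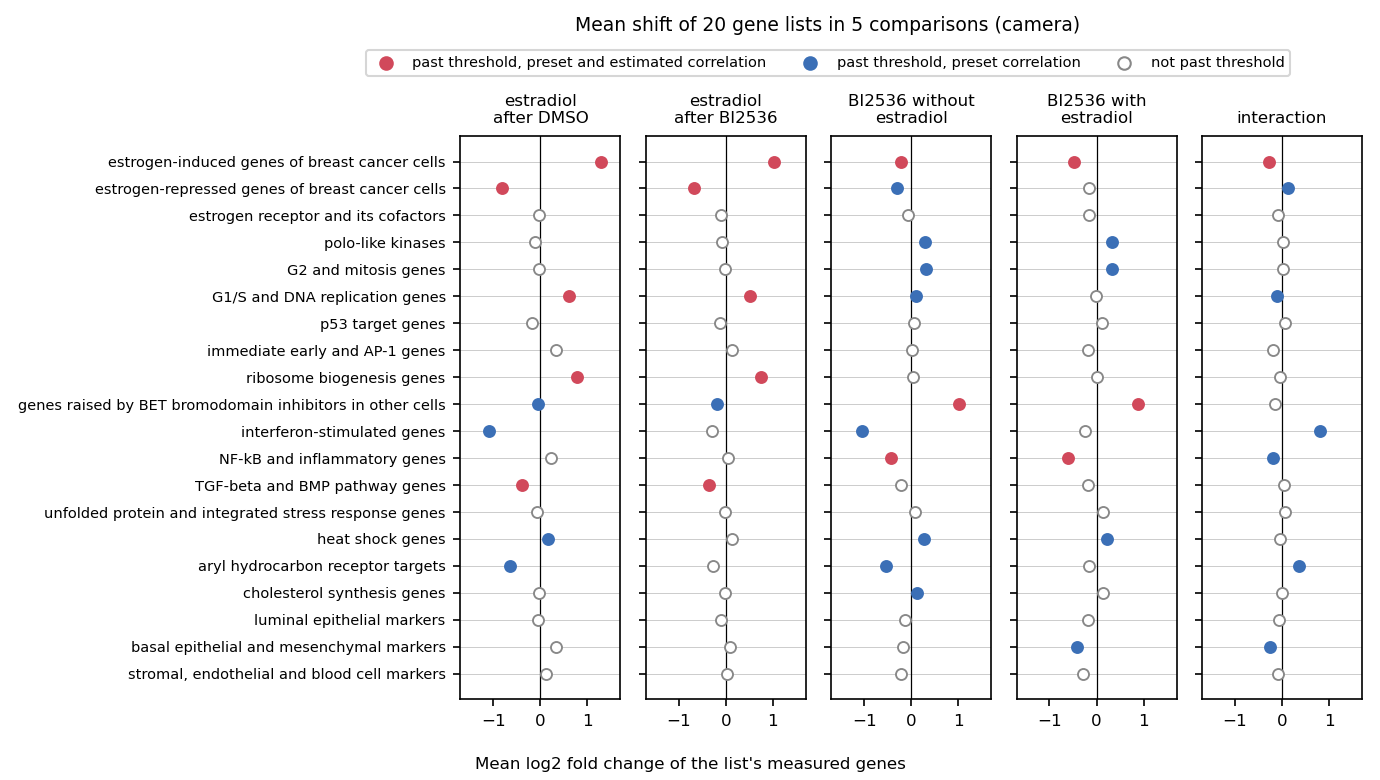
Mean log2 fold change of the measured members of each of the 20 gene lists (x axis) in the 5 comparisons, coloured by whether camera passed the threshold with the preset correlation alone, also with an estimated correlation, or not. Genes raised by BET inhibitors in other cells stand at 1.03 and 0.89 in the BI2536 comparisons, and estrogen-induced genes at 1.29 and 1.02 in the estradiol comparisons.

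The BI2536 comparisons without and with estradiol also share no array, but they too take each gene's spread from the same fit. 1660 genes rose and 1768 fell in both, where independent lists would share 236.5 and 268.7, and 11 were called in opposite directions (r = 0.666 across genes, which are not independent replicates).

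**Figure D3:**
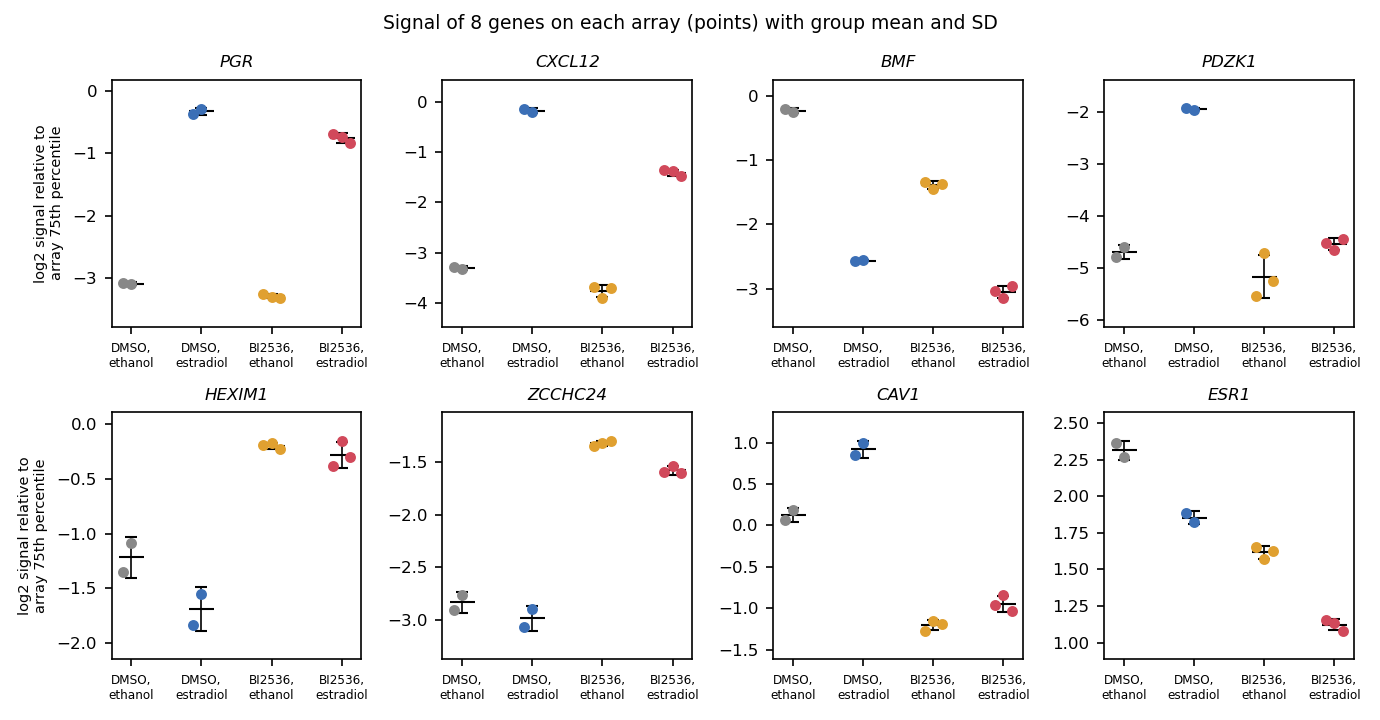
Log2 signal relative to the array's 75th percentile (y axis) of PGR, CXCL12, BMF, PDZK1, HEXIM1, ZCCHC24, CAV1 and ESR1 in the 4 groups (x axis), where points are arrays and bars the mean ± SD (n = 2 or 3). PGR stands near -0.33 with estradiol after DMSO and near -0.75 after BI2536, and HEXIM1 is higher in both BI2536 groups than in both DMSO groups.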

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

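In this part all tests of an explanation were chosen after the result they weigh had been seen, except the counts over other splits of the arrays. No group held 4 samples, and no test for an outlying array was run. The test of the histone members replaced 2 earlier forms, also made after the result was seen.

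The estradiol response differed after BI2536 in 65 genes by the test of the interaction, and in 95 of the genes that responded to estradiol. Gene lists that differed by the same test were the estrogen-induced (mean difference -0.27), estrogen-repressed (0.14), G1/S (-0.11), interferon (0.81), NF-kB (-0.18), aryl hydrocarbon receptor (0.37) and basal and mesenchymal (-0.25) lists. With an estimated correlation only the estrogen-induced list held (adjusted p = 0.01), against 0.211, 0.128, 0.128, 0.128, 0.128 and 0.127 for the others in that order. Among named genes the difference was positive for CYP1A1 (1.72), TRIM63 (1.72), P2RY6 (1.35), VTCN1 (1.05), AHRR (0.93), ERC2 (0.74), CATSPERB (0.64), RNF43 (0.62), VIPR1 (0.60) and RIPOR3 (0.53). It was negative for ISL1 (-4.19), NEFH (-4.05), PLA2G4D (-4.03), BNC1 (-4.02), PLAT (-3.45), TFCP2L1 (-2.36), ARHGAP36 (-2.32), PDZK1 (-2.12), PLIN4 (-2.07), UGT2B15 (-2.01), FOS (-1.30), VWF (-1.11), PMAIP1 (-0.98), CCN5 (-0.86) and CD44 (-0.70). TRIM63, NEFH, PLA2G4D, BNC1, PLAT and TFCP2L1 were not well above background in at least 1 group, so their differences are fitted values and no bounds. PLA2G4D, BNC1 and PLAT were well above background only in DMSO with estradiol, and TRIM63 only in DMSO with ethanol. No estradiol response after BI2536 was therefore measured for PLA2G4D, BNC1, PLAT and TRIM63, and their differences rest on dim signals. ISL1 was well above background on only 1 of 3 arrays of BI2536 with estradiol and 1 of 2 of DMSO with ethanol, so its difference also rests on dim signals. All 25 calls were lost with normexp and on slides 1 and 2 alone. P2RY6, NEFH, PLIN4, UGT2B15 and PLAT passed whichever of the 10 arrays was left out, and the calls of FOS and BNC1 were lost without replicate 2 of DMSO with ethanol (adjusted p = 0.0513 and 0.059). The calls of ERC2, CATSPERB, RNF43, VIPR1, RIPOR3, CCN5 and CD44 were lost whichever array was left out. The other 11 were lost in 3 (AHRR) to 9 of the 10 cases. With the slide as a block the calls of CYP1A1 (0.0633), TRIM63 (0.0537), PDZK1 (0.0844), CATSPERB (0.0736) and VWF (0.0646) were lost.

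The first pattern is the weaker estradiol response after BI2536 among genes changed at least 2-fold, with a median difference of -0.34 toward the estradiol change, against -0.06 for all 5748 responsive genes. A slide effect, since slide 3 held no DMSO array, is argued against by medians of -0.35 and -0.31 within slides 1 and 2. A constant offset from scaling is argued against by like medians of -0.33 for induced and -0.34 for repressed genes. A narrower range of signals on the BI2536 arrays would weaken both alike, so these medians cannot decide on it. Compression of dim signals is argued against as the sole cause by 53 of the genes changed at least 2-fold. They were well above background on every array and among the brightest genes tested. Their median was -0.18 (95% interval -0.30 to -0.13 from a bootstrap over genes). That interval treats genes as independent and does not measure the spread between arrays. The median was smaller in size than that of all 309, so a part of the difference may come from dim signals. A biological difference between the BI2536 and DMSO groups is then a hypothesis consistent with these values, and with 1 inhibitor at 1 dose, inhibition of PLK1 and binding to other targets were not separated. The number of genes stays open, since single arrays moved it to between 11 and 75 of the responsive genes, and normexp and slides 1 and 2 alone gave 9 and 4.

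The second pattern is the rise with BI2536 of the listed genes raised by BET bromodomain inhibitors in other cells. Cross-hybridization between histone genes is argued against as the sole cause of the list's rise by HEXIM1, SERPINI1 and ZCCHC24. These are no histone genes and rose by 1.02 or more in both comparisons, which does not bear on the 9 histone members. The SERPINI1 call with estradiol was lost with the slide as a block (0.0605) and in 4 of 10 fits that left out an array (highest adjusted p 0.159). Scaling is argued against by a list shift of at least 0.68 above the median of all genes under 5 scalings, and a slide effect by shifts of at least 0.86 within slides 1 and 2. Changes differed between the 9 histone members (exact permutation p = 0.01, the smallest the 100 regroupings of arrays within each estradiol state allow). The regroupings did not keep arrays of the same slide together. Probes that read the same mixture but differ in background or compression could also change unequally. The test therefore cannot decide whether all 9 probes read the same mixture. Cross-hybridization between near-identical histone genes, whole or partial, stays open for these members. Binding of BI2536 to BET proteins may underlie the rise, as a hypothesis. A PLK1 inhibitor without BET binding, or a BET inhibitor alone, would test that hypothesis, which was not tested here.

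The third pattern is the lower interferon-stimulated genes with estradiol after DMSO and with BI2536 without estradiol, which both rest on the DMSO with ethanol group. A single high sample in that group is argued against by the authors' table, where its 3 samples had list means of 9.22, 9.05 and 9.04 and the highest other sample 8.61, a gap of 0.43. Values near background are argued against by the 14 members well above background on every array. Their shifts were -0.90 ± 0.18 and -0.88 ± 0.21 (standard error over members). That error treats genes as independent, although the list's estimated correlation was 0.242, and does not measure the spread between arrays. A slide effect is argued against by shifts of -0.87 or lower within slides 1 and 2. A feature shared by the 3 samples of that group, treatment included, remains as a hypothesis, and the list's calls had an adjusted p = 0.145 and 0.202 with an estimated correlation.

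For estradiol after BI2536 the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3467 genes and the highest of the others 0 by limma (202 to 1124 genes at an unadjusted p under 0.05, against 5933), so that 1 split reached the real count. For gene lists the real split gave 6 and the highest of the others 7, and 3 splits gave 6 or more. The 3 other splits that part all 3 same-slide pairs gave 4, 6 and 5 lists. Every other split mixes estradiol and ethanol arrays on both sides. Part of the estradiol effect then stays between the sides, and the rest enters the spread within them. Few gene calls were therefore bound to follow, and list calls may carry the estradiol effect. The splits cannot show what grouping without an effect would give, and no conclusion is drawn from them.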

How the results depend on the processing

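Of 953 values of called gene lists under the alternatives 889 kept their direction and side of the threshold and 64 lost the call, and of 8392 values of called genes 7326 kept both, 1063 lost the call and 3 reversed. Of 1427 values of lists that were not called 78 gained a call and 1 reversed, and of 588 of genes 21 gained one. No gene called in the main setting was called in the opposite direction under an alternative where calls were compared, which leaves out the fit of every probe on its own. Except where stated the cause was not tested.

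With normexp the counts of called genes were 1248 and 1161 for estradiol after DMSO and after BI2536, 1516 and 1371 for BI2536 without and with estradiol, and 0 for the interaction by limma (475 at an unadjusted p under 0.05). Interaction calls among responsive genes numbered 9, the median difference was -0.28, shared estradiol calls 850 and interaction lists 11. Each of the 3 reversed genes was not well above background in at least 1 group, so their values are fitted and no bounds. Normexp reversed SERPINI1 for estradiol after DMSO (-0.12 against 1.89), WNT5A for estradiol after BI2536 (0.042 against -1.73), PLAT in the interaction (0.10 against -3.45), and the test direction of G2 and mitosis genes in the interaction (0.015 against 0.014, adjusted p = 0.0368 against 0.667). The median of all genes was -0.17, 0.05, -0.11, 0.10 and 0.12 in the 5 comparisons against -0.04, -0.03, -0.00, -0.01 and 0.01, and 61.4% of calls for estradiol after BI2536 were higher against 48%. Under median scaling the median of all genes was 0.09 and 0.10 for BI2536 without and with estradiol. The authors' table with 11 samples gave 172 interaction calls among responsive genes. No filter on dim probes gave 36 interaction calls, and a filter on every array a median difference of -0.29.

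The slide as a fixed block, which pairs the replicates, gave 5967, 5998 and 118 (both estradiol comparisons and the interaction) and 4387 shared calls. It changed no list or named gene call beyond those printed with their blocked p, except losses of SERPINI1 for estradiol after DMSO (0.0677) and for BI2536 with estradiol (0.0605), EGR3 (0.0625), WDR43 (0.0556) and SC5D (0.0501) with estradiol, and UTP20 without it (0.0617). As a random block it gave 5982, 5968 and 259, with 280 among responsive genes, 4348 shared, and 30.1% higher interaction calls against 18.5%. Only the groups compared in the fit gave 231 for estradiol after DMSO (65.8% higher against 49.6%), 2690 and 2734 for BI2536 without and with estradiol, with fewer arrays for the spread. Only slides 1 and 2, chosen after seeing the data, gave with fewer arrays 1361 for estradiol after BI2536, 3010 and 2920 for BI2536, 0 for the interaction by limma (1249 at an unadjusted p under 0.05), 4 among responsive genes and 1212 shared. Camera with an estimated correlation called 5 lists for estradiol after DMSO, 3 for each BI2536 comparison and 1 for the interaction, and fry 15, 11 and 15 for both estradiol comparisons and BI2536 with estradiol.

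Leaving out each array, which leaves fewer samples, gave 2114 to 3384 and 2310 to 3127 for estradiol after DMSO and after BI2536, 2890 to 4523 and 2735 to 4241 for BI2536 without and with estradiol, 11 to 32 for the interaction, 11 to 75 among responsive genes, medians of -0.35 to -0.25, and 1647 to 2136 shared. List counts were 8 to 9, 6 to 7, 8 to 11, 7 to 9 and 5 to 8. Interaction calls were higher in 7.1% without replicate 1 of DMSO with estradiol and 6.5% without replicate 2 of BI2536 with ethanol. A group left with 1 array was assumed to vary like the others.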

Other observations

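The gene families here and their tests were chosen after the data were seen. The overlap hypothesis and its bound were written before its result.

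Families of genes that share a symbol prefix, 208 with at least 10 members, were tested with camera in each comparison, and none of those named here held with an estimated correlation. With estradiol after DMSO, 12 of 23 NUP genes, most of which encode nucleoporins, rose and none fell (adjusted p = 1.38e-05, and adjusted p = 0.178 with an estimated correlation), and after BI2536 14 rose (2.43e-07 and 0.11). Of 36 DDX genes, RNA helicases, 15 rose and 2 fell after DMSO (0.000544 and 0.668) and 16 rose and 1 fell after BI2536 (4.91e-05 and 0.303). Of 11 UTP genes, factors of ribosomal RNA processing, 8 rose and none fell after DMSO (0.000142 and 0.225).

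With BI2536, 15 of 38 CEP genes, centrosomal proteins, rose and 1 fell without estradiol (adjusted p = 0.00117, and 0.662 with an estimated correlation), and 13 rose and 2 fell with it (0.00652 and 0.738). PARP genes fell, 7 of 12 in each comparison (0.0148 and 0.766, then 0.0354 and 0.771). PCDHB genes, clustered protocadherins, fell in 7 of 10 cases without and 6 with estradiol (0.00433 and 0.739, then 0.00398 and 0.738), and in 4 of 10 with estradiol after DMSO (0.0171 and 0.722). PCDHB genes are close in sequence, so which of them fell is uncertain. Over 5 scalings the mean shifts in these comparisons kept their sign, with CEP between 0.14 and 0.32 without and 0.19 and 0.29 with estradiol, and PCDHB between -0.32 and -0.22 without and -0.34 and -0.21 with estradiol.

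A further hypothesis was that BI2536 lowers the genes that estradiol raises. In the additive model 750 genes rose with estradiol and fell with BI2536, 1.77 times the 424.6 of independent lists. The other 3 combinations of directions were also over-represented, with 574 against 430.8 for rises in both, 845 against 532 for genes that fell with estradiol and rose with BI2536, and 986 against 524.3 for falls in both. Across genes the effects correlated at r = -0.035. The hypothesis required both an excess in that combination and a correlation below -0.1, so the result was negative. Genes called for either treatment were more often called for the other in any direction. Both effects were tested against the same estimate of each gene's spread, so genes with little spread pass both tests more easily. The excess over independent lists may therefore reflect power alone.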
